A study of Arabidopsis thaliana with 60 samples.

How the data were processed

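Gene counts of 60 libraries were taken as deposited by the authors, who, per the submitters' processing notes, had aligned the reads with STAR 2.5.2b to TAIR10. From each file the fourth column was used, because it held 93.6 to 96.4% of the counts assigned to either strand. Rows naming no gene, such as unmapped, multiply mapped or ambiguous reads, held 5.58 to 11.89% of all counts and were left out, which left 32833 genes. Of these, 32548 matched the TAIR10.1 gene table and 10804 carried a symbol; a gene without a symbol is named by its locus. The library totals ran from 12146529 to 94077078 counts.

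The labels number the replicates of every group 1 to 3 but do not state that they were separate cultures, so the p-values measure the spread between these samples, which may be technical. No pair of libraries within a group was a duplicate: the lowest chi-square per degree of freedom between 2 replicates was 15.48, where counting error alone would give about 1. The sequencing run of each library was known only from the file names. In the shy2-2 line the DEX and DMSO libraries of 0, 2, 4 and 6 h came from separate runs and both arms of 1 h from the same run. In the slr-1 line no DEX group shared a run with the DMSO group of its own time. Run could therefore not be a term of the model. Where runs are said below to cancel, this holds for a run difference of the same log2 size at the times compared.

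The groups, the contrasts, the thresholds, the gene lists, the rule for naming genes and the first set of alternatives were chosen before the data were examined. Each line was fitted by itself (30 libraries, 10 groups) in edgeR 4.0.16 with genes kept by filterByExpr on the group, TMM factors, robust dispersions and the quasi-likelihood test. Tested were 21902 genes in shy2-2, 21864 in slr-1 and 22268 in the fit of both lines, which was used only for differences between the lines. The residual degrees of freedom of these fits were 20, 20 and 40, and the biological coefficients of variation 0.201, 0.181 and 0.192. All p-values of genes were adjusted by the Benjamini-Hochberg method over all genes tested in a contrast. A gene was said to rise, fall or differ where the adjusted p was under 0.05. In DEX against DMSO, rise and fall mean higher and lower in DEX at that time, not a change over time. For the change of the auxin response they mean a more positive and a more negative response under DEX. Contrasts were the auxin response (1, 2, 4 or 6 h against 0 h of IAA in DMSO), DEX against DMSO at each time, and the change of the auxin response by DEX, that is the mean of 2, 4 and 6 h minus 0 h in DEX, less the same in DMSO. For the difference between the lines the shy2-2 contrast less the slr-1 contrast was tested. The TMM factors ran from 0.945 to 1.049.

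A gene was named by rank where the adjusted p was under 0.05, the log2 fold change was at least 1 in size, the mean over the compared libraries was at least 5 CPM (counts scaled to a common library total with the TMM factors) and the CPM of the 2 groups did not overlap, which 3 libraries against 3 do by chance in 10% of genes. From the 10 largest rises and 10 largest falls the first ones are named in rank order of the fitted fold. Where a group held few or no counts that order is not one of measured size. The overlap condition did not apply to the contrasts of 4 or more groups. IAA3, IAA14, GATA23, LBD16, LBD29, EXPA1, GH3.3, IAA19 and IAA5 could be named whatever their values, and up to 4 members of each list by adjusted p. Genes outside this rule are said to be so where they appear. Errors given with ± are standard errors of the log2 fold change with n = 3 libraries per group, unless SD is stated. They were derived as the size of the log2 fold change over the square root of the quasi-likelihood F value. The spread behind them was estimated over all libraries of the fit. The 95% intervals of differences between the lines were built on these errors with 40 degrees of freedom. Where a group held no counts the fold is given as a bound, with 3 counts over the 3 libraries as the floor; where a group held 1 to 3 counts the ratio of the pooled counts is given with its exact binomial 95% interval, which covers counting error only.

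The 20 gene lists hold 254 distinct genes and cover Aux/IAA repressors, lateral root initiation, auxin transport, auxin metabolism, cytokinin, ethylene, separation of overlying tissue, DNA replication, mitosis, endodermis, suberin, xylem, phloem, root hair, root cap, photosynthesis, clock, heat shock, touch, wounding and jasmonate (as 1 list), and detoxification. Lists were compared with all other genes by limma's camera (limma 3.58.1) with a preset correlation of 0.01 and, beside it, with the correlation estimated from the data; the p-values were adjusted over the lists of a contrast. Of 420 tests of a list in a contrast 116 passed with the preset and 32 with the estimated correlation, so a list p-value from the preset alone is given together with the other. The rotation test fry was also run, which asks if the genes of a list move on balance one way and does not compare them with other genes. Sets of genes that answered to auxin in DMSO of one line with a log2 fold of at least 1 (mean of 2, 4 and 6 h) were tested in the other line only.

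The pipeline was tested on simulated data with the dispersions and depths of the real libraries. In DEX against DMSO of shy2-2 at 6 h, over 21775 genes, 37.3, 55.2 and 81.8% of the genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 7 false calls among 123. For the change of the auxin response by DEX, over 21772 genes, these shares were 23.9, 59.7 and 80.3%, with 5 false calls among 114. The list of 20 changed genes was called and 0 of 19 unchanged lists were, by camera with the preset correlation. The genes were simulated independently of each other. False list calls that come from correlated genes could therefore not show in this test.

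The alternatives chosen before the data were examined were RLE size factors in place of TMM, no expression filter beyond 1 read, DESeq2 1.42.0 in place of edgeR, a replicate block, a fit of only the compared groups, and the leaving out of each library in turn. Added after the data were seen were the deposited counts of both strands (made without regard to strand), a fit without 7 libraries high in photosynthetic RNA, the differences between the lines at 4 and 6 h, and 2 further gene lists, for transporters of the stele and for aliphatic glucosinolate synthesis. The camera p-values of these 2 lists were adjusted over the 2 alone. Positions are TAIR10.1 coordinates. Further software was R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.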

Results

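RNA was sequenced from lower root segments of Arabidopsis seedlings of 2 lines, which carry a stabilised Aux/IAA repressor fused to the glucocorticoid receptor domain under the promoter of GATA23. The line pGATA23::shy2-2-GR, here shy2-2, holds stabilised IAA3 and the line pGATA23::slr-1-GR, here slr-1, stabilised IAA14; neither name stands for the native mutant. Dexamethasone (DEX) lets the fusion enter the nucleus. Seedlings were held for 22 h on 10 µM NPA, which blocks auxin transport, were given DEX or the solvent DMSO for 2 h, and then 10 µM of the auxin IAA. RNA was taken after 0, 1, 2, 4 and 6 h of IAA, from about 200 pooled segments per sample. The harvest text of the labels names only 0, 2, 4 and 6 h, so it is open if the 12 samples labelled 1 h belong to the same experiment. The 60 libraries form 20 groups of 3 (2 lines, 2 treatments, 5 times), with no time course without IAA and no DEX treatment of plants without a fusion gene. What is called the auxin response therefore includes any effect of elapsed time, which cannot be told apart from that of auxin. The median library held 42975836 counts in shy2-2 (20112051 to 57076338) and 39734826 in slr-1 (12146529 to 94077078).

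The genes followed throughout were IAA3 (AT1G04240, chromosome 1, 1128149 to 1129689, minus strand) and IAA14 (AT4G14550, chromosome 4, 8347822 to 8350263, minus strand). GATA23 (AT5G26930, chromosome 5, 9479424 to 9480200, plus strand) encodes a GATA factor of founder cells. LBD16 (AT2G42430, chromosome 2, 17663353 to 17665337, plus strand) and LBD29 (AT3G58190, chromosome 3, 21548484 to 21549572, minus strand) encode LOB-domain factors that act downstream of ARF7 and ARF19. EXPA1 (AT1G69530, chromosome 1, 26141726 to 26143538, plus strand) encodes an expansin of the cell wall and GH3.3 (AT2G23170, chromosome 2, 9863855 to 9866562, minus strand) an enzyme that conjugates IAA to amino acids. IAA19 (AT3G15540, chromosome 3, 5264001 to 5265695, plus strand) and IAA5 (AT1G15580, chromosome 1, 5365512 to 5366497, minus strand) encode further Aux/IAA repressors. IAA3 and IAA14 also served to check the line labels, since reads of a fusion gene count toward its native gene. IAA3 stood at 21.7 ± 5.5 CPM (SD, n = 3) in shy2-2 and 12.3 ± 2.5 in slr-1 in DMSO at 0 h, a ratio of 1.77. IAA14 stood at 22.6 ± 2.8 and 30.9 ± 0.3, a ratio of 0.73. By group means IAA3 was higher in shy2-2 and IAA14 higher in slr-1 in 10 of 10 pairs of groups with the same treatment and time. The libraries overlapped in 7 of the pairs for IAA3 and in 3 for IAA14, and the ratio for IAA3 was as low as 1.05 in DEX at 4 h.

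How did roots of the shy2-2 line answer to auxin without DEX? Within 1 h of IAA 13 of 25 genes of lateral root initiation and 22 of 28 Aux/IAA genes had risen. PUCHI (AT5G18560), which encodes an AP2 factor of primordium patterning, had no counts at 0 h and rose at least 588-fold at 1 h (n = 3 libraries per group). GAD4 (AT2G02010), a glutamate decarboxylase gene, rose by a log2 fold of 8.86 ± 0.57 and IAA5 by 8.80 ± 0.58, followed by AT1G30190 at 8.64 ± 0.55. Genes ranked here and later had a mean of at least 5 CPM and, between 2 groups, no overlap of their libraries. EXPA17 (AT4G01630), an expansin gene, fell by 6.41 ± 0.43, AT1G05650 by 6.04 ± 0.49 and AT5G17960 by 4.22 ± 0.46. GATA23 rose by 5.75 ± 0.31, LBD16 by 3.28 ± 0.14, LBD29 by 7.55 ± 0.37, GH3.3 by 5.75 ± 0.22 and IAA19 by 5.49 ± 0.40. IAA3 rose by 2.38 ± 0.26, IAA14 by 2.20 ± 0.18 and EXPA1 by 1.47 ± 0.27, the last with an adjusted p of 0.00018 in edgeR's quasi-likelihood test. The 1 h libraries came from another run than those of 0 h, while the later times shared a run with 0 h.

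Among gene groups at 1 h in shy2-2, the Aux/IAA repressors rose in 22 of 28 tested genes and fell in 0. IAA1 (AT4G14560) rose by 3.14 ± 0.14 and IAA11 (AT4G28640) by 3.73 ± 0.18. Of 25 genes of lateral root initiation 13 rose and 2 fell, among them the auxin response factor gene ARF19 (AT1G19220) at 2.31 ± 0.08. Adjusted over the list alone these counts were 14 and 2. Detoxification genes rose in 5 of 6 (6 adjusted over the list alone). CYP81D8 (AT4G37370), a cytochrome P450 gene, rose by 2.64 ± 0.24 and the alternative oxidase gene AOX1A (AT3G22370) by 1.02 ± 0.09. By camera these 3 lists had adjusted p values of 7.4e-20, 3.8e-08 and 1.8e-06, and of 0.0059 each with an estimated correlation. Auxin transport genes rose in 11 of 16 and fell in 0. The kinase gene PID (AT2G34650) stood at 2.46 ± 0.14 and the efflux carrier gene PIN3 (AT1G70940) at 1.98 ± 0.12. Their camera result did not hold up under the other setting (adjusted p = 3.8e-08, adjusted p = 0.052 with an estimated correlation).

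Auxin metabolism genes of shy2-2 rose in 9 of 17 at 1 h and fell in 4, with GH3.2 (AT4G37390) at 5.30 ± 0.21 (camera adjusted p = 0.0053, adjusted p = 0.16 with an estimated correlation). By adjustment over the list alone 9 rose and 6 fell. Cytokinin genes rose in 9 of 20 and fell in 2 (0.0014, 0.25 with an estimated correlation). The cytokinin oxidase genes CKX6 (AT3G63440) and CKX3 (AT5G56970) stood at 3.31 ± 0.26 and 3.14 ± 0.27. Ethylene genes rose in 8 of 14 and fell in 1, with the ACC synthase gene ACS11 (AT4G08040) at 2.99 ± 0.29 (0.0036, 0.063 with an estimated correlation). Genes of touch, wounding and jasmonate rose in 4 of 14, with the calmodulin-like gene TCH3 (AT2G41100) at 3.83 ± 0.24 (0.069). Heat shock genes rose in 4 of 9, with HSFA2 (AT2G26150) at 3.48 ± 0.40 (0.18), and 1 fell when adjusted over the list alone, and the clock genes rose in 4 and fell in 2 of 17 (0.33). By gene number, 3455 genes rose and 2886 fell at 1 h, 3468 and 2548 at 2 h, and 5367 and 3803 at 4 h in edgeR's quasi-likelihood test.

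By 6 h in shy2-2, 5767 genes rose and 4388 fell. PUCHI and AT2G03740 had no counts at 0 h, and AT2G03740 rose at least 705-fold. LBD19 (AT2G45410), another LOB-domain gene, rose from 1 count by a ratio of 3600 (645 to 142000). With so few counts at 0 h these rises have no measured order. Among the falls AT1G05650 had a log2 fold of -8.61 ± 0.62, AT1G05660 -7.15 ± 0.68, AT1G19900 -6.79 ± 0.43 and CER4 (AT4G33790), a gene of fatty acyl reduction, -6.71 ± 0.61. SKOR (AT3G02850), which encodes the potassium channel of xylem loading, ranked sixth among the falls at -6.51 ± 0.26. LBD16 stood at 3.67 ± 0.14, GATA23 at 5.51 ± 0.31, LBD29 at 7.35 ± 0.37, GH3.3 at 5.72 ± 0.22, IAA19 at 5.99 ± 0.41 and IAA14 at 2.13 ± 0.18. The rise of EXPA1 went on: its log2 fold was 2.80 ± 0.28 at 2 h, 4.34 ± 0.30 at 4 h and 4.84 ± 0.31 at 6 h, from 14.4 ± 1.43 CPM at 0 h to 405 ± 35.3 CPM (SD).

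Genes of lateral root initiation rose in 20 of 25 at 6 h in shy2-2 and fell in 2 (camera adjusted p = 1.1e-10, adjusted p = 0.0043 with an estimated correlation), or in 21 adjusted over the list alone. Aux/IAA genes rose in 22 of 28 and fell in 1 (2 adjusted over the list alone; 7.2e-11, 0.054 with an estimated correlation). Genes for the separation of overlying tissue rose in 4 of 6, among them the auxin influx carrier gene LAX3 (AT1G77690) by 2.09 ± 0.18 (0.0043, 0.29 with an estimated correlation). Suberin genes rose in 5 of 5, with the feruloyl transferase gene ASFT (AT5G41040) at 3.43 ± 0.48 (0.0086, 0.34 with an estimated correlation). Root hair genes fell in 7 of 7, such as EXPA7 (AT1G12560) by 1.40 ± 0.19 and RSL4 (AT1G27740) by 1.31 ± 0.21 (0.003, 0.29 with an estimated correlation). Endodermis genes fell in 6 of 9, for example the Casparian strip gene CASP4 (AT5G06200) by 1.03 ± 0.20 (0.027, 0.4 with an estimated correlation). Xylem genes fell in 5 of 6, with the cellulose synthase gene CESA8 (AT4G18780) at -0.96 ± 0.26 (0.03, 0.36 with an estimated correlation). Phloem genes fell in 2 of 3, with the sucrose carrier gene SUC2 (AT1G22710) at -1.12 ± 0.19 (0.052). DNA replication genes rose in 4 of 17 and fell in 2 (camera adjusted p = 0.41), and mitosis genes rose in 7 of 18 and fell in 1 (0.13). Clock genes rose in 8 of 17 and fell in 7 (0.84), or 9 and 8 adjusted over the list alone. Camera looks for a shift one way, so its p-value does not register clock genes that moved both ways. There was no time course without IAA, so elapsed time and auxin cannot be told apart here.

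How did the slr-1 line answer to auxin without DEX? GAD4 rose from 3 counts by a ratio of 1310 (447 to 6350) within 1 h and PUCHI from 3 counts by a ratio of 593 (203 to 2880). Next came AT4G37295 at 9.04 ± 0.48, IAA5 at 8.08 ± 0.43 and AT1G30190 at 7.98 ± 0.38 (n = 3 libraries per group). AT1G05650 led the falls at -6.74 ± 0.49. GATA23 rose by 5.21 ± 0.24, LBD16 by 3.41 ± 0.13, LBD29 by 7.81 ± 0.24, GH3.3 by 6.15 ± 0.31, IAA19 by 5.57 ± 0.17, IAA3 by 2.21 ± 0.22, IAA14 by 2.33 ± 0.10 and EXPA1 by 1.45 ± 0.28. Aux/IAA genes rose in 23 of 28 (24 adjusted over the list alone) and fell in 0 (camera adjusted p = 5.7e-22, adjusted p = 0.00059 with an estimated correlation). In lateral root initiation 13 of 25 genes rose and 3 fell (2.1e-07, 0.039 with an estimated correlation), and detoxification genes rose in 6 of 6 (1.2e-06, 0.0038 with an estimated correlation). In total 3449 genes rose and 2492 fell at 1 h, 4241 and 3047 at 2 h, and 6170 and 5287 at 4 h in edgeR's quasi-likelihood test.

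By 6 h in slr-1, 6387 genes rose and 5533 fell. PUCHI rose from 3 counts by a ratio of 3070 (1050 to 14900), LBD19 from 1 by 2520 (453 to 99800) and AT4G37295 from 5 by 1230 (528 to 3800). PGAZAT (AT2G41850), a polygalacturonase gene, rose at least 1910-fold, AT2G03740 at least 630-fold and AT2G43860 at least 479-fold. SRS5 (AT1G75520), a SHI-related factor gene, rose at least 381-fold and UMAMIT15 (AT5G13670), of an amino acid transporter family, at least 331-fold, each of these 5 from no counts at 0 h, so the rises have no measured order. AT1G05650 fell at least 722-fold. LBD16 stood at a log2 fold of 3.70 ± 0.13, GATA23 at 5.02 ± 0.24, LBD29 at 7.36 ± 0.23, GH3.3 at 5.85 ± 0.31, IAA19 at 5.93 ± 0.17 and EXPA1 at 4.80 ± 0.31, while SKOR fell by 7.08 ± 0.26. Mitosis genes rose in 15 of 18 and fell in 1, such as the kinase gene CDKB2;1 (AT1G76540) by 2.01 ± 0.17 (camera adjusted p = 0.00033, adjusted p = 0.41 with an estimated correlation). DNA replication genes rose in 14 of 17 and fell in 2, such as the ribonucleotide reductase gene RNR1 (AT2G21790) by 1.24 ± 0.15 (0.015, 0.5 with an estimated correlation). Endodermis genes fell in 9 of 9, among them CASP4 by 2.24 ± 0.18 (0.00033, 0.3 with an estimated correlation), and root hair genes in 7 of 7 (0.00088, 0.29 with an estimated correlation). Aux/IAA genes rose in 21 of 28 and fell in 2 (3.2e-10, 0.033 with an estimated correlation). For lateral root initiation 19 of 25 genes rose and 3 fell (3.7e-09, 0.035 with an estimated correlation). All DMSO libraries of slr-1 at 0 h came from another run than those at the later times, while shy2-2 had 0, 2, 4 and 6 h in the same run. Of the genes that passed in slr-1, 98.9, 98.8 and 96.3% had the same sign in shy2-2 at 2, 4 and 6 h.

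Some libraries carried much RNA of photosynthesis genes. In 7 of the 60 the mean log2(CPM + 1) of the 9 genes of that list was above 6 (lowest 6.62), against at most 5.48 in the other 53. In shy2-2 these were DEX 0 h replicate 2 (8.15), DEX 4 h replicate 3 (6.72) and DMSO 2 h replicate 2 (8.1), and in slr-1 DEX 0 h replicates 1 (8.01) and 2 (7.43) and DMSO 2 h replicates 1 (6.62) and 3 (6.69). The shoot identity genes YAB3 (AT4G00180) and AFO (AT2G45190), which encode YABBY factors of leaf polarity, reached 2.2 and 2.04 CPM in slr-1 DEX 0 h replicate 1 against a median of 0 over all libraries. A fit without the 7 libraries leaves slr-1 DEX 0 h and slr-1 DMSO 2 h with 1 library each. In contrasts with these groups a lower count of genes can therefore come from lost replicates as well as from the RNA removed.

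**Figure D1:**
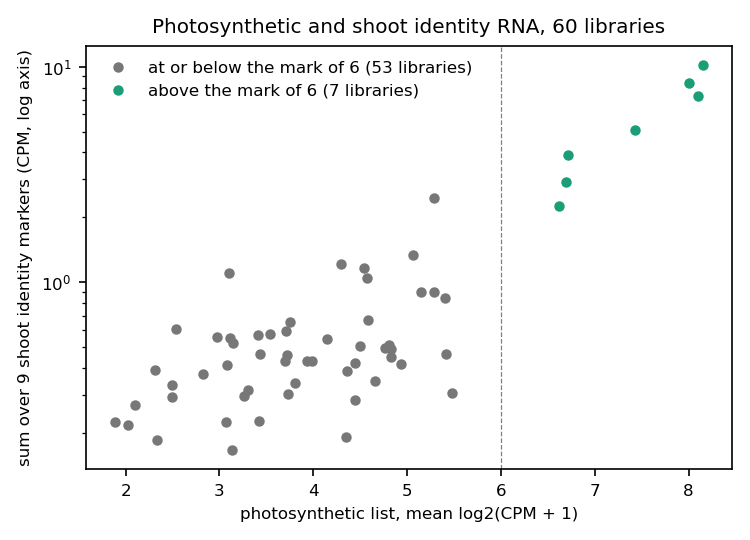
Mean log2(CPM + 1) of 9 photosynthesis genes (x axis) against the summed CPM of 9 shoot identity genes (y axis, log scale) in each of the 60 libraries. Above the mark of 6 lay 7 libraries, and 6 of them were among the 7 highest in shoot identity genes; 53 lay at or below it.

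Did DEX act before auxin was given? At 0 h GATA23, whose promoter drives the fusion, held 2 counts in DEX and 59 in DMSO in shy2-2 (ratio 0.0664, 0.00786 to 0.251; adjusted p = 0.12 in edgeR's quasi-likelihood test, not past the test). It held 2 and 75 in slr-1 (ratio 0.0241, 0.00287 to 0.0903; adjusted p = 1.4e-05). LBD16 did not pass at 0 h in either line (-0.40, adjusted p = 1, and -0.63, adjusted p = 0.12). In shy2-2 edgeR's quasi-likelihood test called 0 genes, and DESeq2 called 6. At unadjusted p under 0.05 in edgeR's test were 728 of 21902 genes, fewer than chance alone would give. The test may thus be too strict here, and its 0 calls do not show that DEX had no effect. In slr-1 edgeR's test called 5 genes with 1281 at unadjusted p under 0.05, among them GATA23. The others, outside the naming rule and chosen after their values were seen, were the xyloglucan hydrolase gene XTH7 (AT4G37800) at 4.81 ± 0.62, AT1G11330 at 1.01 ± 0.17, LBD17 (AT2G42440) at -1.41 ± 0.25 and LBD14 (AT2G31310) at -2.66 ± 0.43. That count was 0 when only the compared groups were fitted, 2 without the 7 libraries high in photosynthetic RNA, 2 without slr-1 DEX 0 h replicate 1, replicate 2 or DMSO 0 h replicate 2, 3 without DMSO 0 h replicate 3 and 160 without DEX 0 h replicate 3. In shy2-2 it was 2 without DEX 0 h replicate 3. The calls of all 5 genes in slr-1 were lost when only the compared groups were fitted. The calls of AT1G11330, LBD14 and LBD17 were also lost without the 7 libraries, which include 2 of the 3 slr-1 DEX 0 h libraries, and without slr-1 DEX 0 h replicate 1 or 2 or DMSO 0 h replicate 2 or 3, and that of LBD17 without DEX 0 h replicate 3 too. GATA23 and XTH7 kept theirs in these fits, XTH7 at 3.18 without the 7 libraries.

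What did DEX change 1 and 2 h after auxin? At 1 h in shy2-2, where both treatments came from the same run, 22 genes were higher and 26 lower in DEX in edgeR's quasi-likelihood test. In slr-1 46 were higher and 82 lower. When only the compared groups were fitted 7 genes passed in shy2-2 and 28 in slr-1. GATA23 was lower by a log2 fold of 4.69 ± 0.29 in shy2-2 and by 4.87 ± 0.22 in slr-1 (n = 3 libraries per group). Higher in shy2-2 were CYP90D1 (AT3G13730), a gene of brassinosteroid synthesis, at 2.33 ± 0.21 and SKOR at 1.81 ± 0.20. Both calls were lost when only the compared groups were fitted. PUCHI was lower by 2.18 ± 0.38, a call lost without shy2-2 DEX 1 h replicate 1 or 2 or DMSO 1 h replicate 2, and LBD17 by 1.95 ± 0.22. In slr-1 SKOR was higher in DEX by 2.59 ± 0.20, AT1G49570 by 2.39 ± 0.27 and the zinc exporter gene HMA2 (AT4G30110) by 2.21 ± 0.24. AT2G42150 was lower by 3.04 ± 0.15. LBD16 was lower at -0.96 ± 0.13 in shy2-2 and -1.10 ± 0.12 in slr-1, while EXPA1 did not pass (-0.10 and -0.37). In slr-1 IAA14 was lower by 0.72 ± 0.09, a call lost when only the compared groups were fitted. Its counts do not separate the native gene from the fusion: in DMSO it stood at 103.6 CPM in shy2-2 and 153.8 in slr-1, in DEX at 89.1 and 94.3. In lateral root initiation 4 of 25 genes were lower in shy2-2 (7 adjusted over the list alone; camera adjusted p = 5.4e-12, adjusted p = 0.0021 with an estimated correlation) and 8 of 25 in slr-1 (9 adjusted over the list alone; 1.7e-19, 0.0017 with an estimated correlation), with 0 higher in both.

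At 2 h 58 genes were higher and 72 lower in DEX in shy2-2, and 92 higher and 251 lower in slr-1. When only the compared groups were fitted 21 and 100 passed, and without the 7 libraries high in photosynthetic RNA 99 and 151. In shy2-2 the treatments came from separate runs at 2 h. In the difference to 0 h, in which the runs cancel, 22 genes passed, 21 of them among the 130. That count was 11 without DEX 0 h replicate 2, 14 and 13 without DEX 2 h replicates 2 and 3, 12 and 13 without DMSO 0 h replicates 2 and 3, 12 and 13 without DMSO 2 h replicates 1 and 3 and 10 without the 7 libraries. In shy2-2 SKOR was higher in DEX by 2.63 ± 0.20 and AT4G30460 by 2.45 ± 0.26, and GATA23 was lower by 4.45 ± 0.30. LBD33 (AT5G06080), another LOB-domain gene, fell by 2.06 ± 0.37, a call lost when only the compared groups were fitted and without shy2-2 DEX 2 h replicate 1 or DMSO 2 h replicate 3. In slr-1 AT1G49570 was higher in DEX by 4.03 ± 0.29 and SKOR by 3.87 ± 0.22. GATA23 was lower by 4.84 ± 0.23 and AT2G42150 by 3.01 ± 0.15. LBD16 fell by 1.00 ± 0.13 in shy2-2 and by 1.53 ± 0.12 in slr-1. Of the genes of lateral root initiation 5 of 25 fell in shy2-2 (camera adjusted p = 9.7e-07, adjusted p = 0.037 with an estimated correlation) and 8 of 25 in slr-1 (2.2e-15, 0.0062 with an estimated correlation). The counts of these early times moved by more than 1.5-fold with single libraries. For 130 genes at 2 h in shy2-2 they were 76, 80 and 69 without DEX replicates 1, 2 and 3, and 70 and 52 without DMSO replicates 1 and 3. For 343 genes at 2 h in slr-1 they were 201, 173 and 166 without DEX replicates 1, 2 and 3, and 170 and 196 without DMSO replicates 2 and 3. For 128 genes at 1 h in slr-1 they were 71 and 85 without DEX replicates 1 and 2, and 72 and 73 without DMSO replicates 2 and 3.

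**Figure D2:**
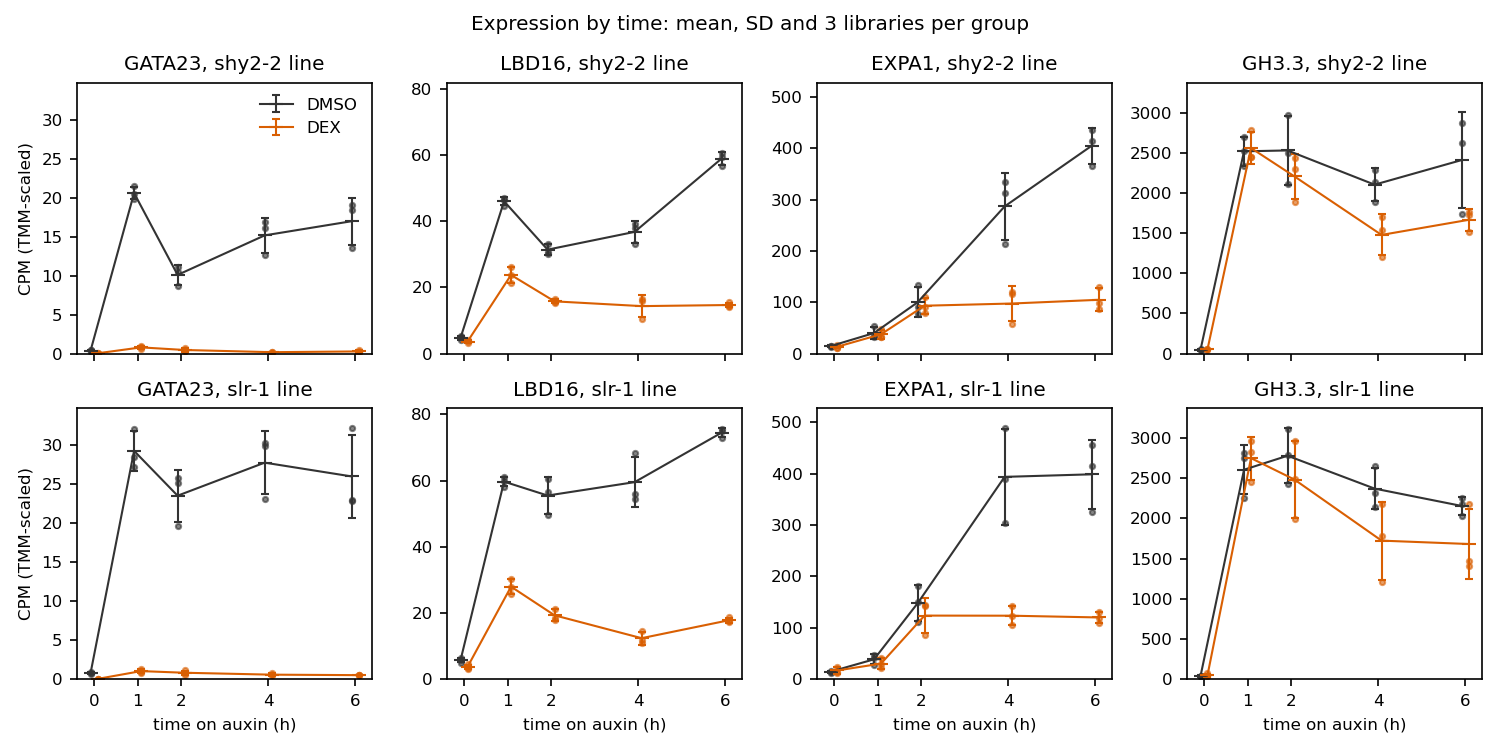
CPM of GATA23, LBD16, EXPA1 and GH3.3 (y axis) by hours of IAA (x axis) in DMSO (black) and DEX (orange), as mean, SD and 3 libraries per group, in both lines. EXPA1 rose to 405 CPM in DMSO and 105 CPM in DEX at 6 h in shy2-2.

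What did DEX change later, at 4 and 6 h of auxin, in shy2-2? At 4 h 540 genes were higher and 1835 lower, and at 6 h 1868 higher and 3051 lower in edgeR's quasi-likelihood test. At 6 h AT4G30460 was higher by a log2 fold of 4.80 ± 0.31, SKOR by 4.67 ± 0.24 and AT3G01260 by 4.57 ± 0.34. Next were scpl31 (AT1G11080), a serine carboxypeptidase-like gene, at 4.36 ± 0.60 and NRT1.5 (AT1G32450), a gene of nitrate loading into the xylem, at 4.13 ± 0.20 (n = 3 libraries per group). Lower were AT2G15590 at -6.45 ± 0.35, GATA23 at -5.96 ± 0.33, AT5G17340 at -5.21 ± 0.42, AT2G03740 at -4.93 ± 0.46 and RBK2 (AT3G05140), a gene of a ROP-binding kinase, at -4.05 ± 0.25. FLP (AT1G14350), a MYB factor gene, ranked seventh at -3.87 ± 0.13. NRT1.5 went from 952 ± 287 CPM (SD) at 0 h to 27.8 ± 3.33 in DMSO and 497 ± 60.6 in DEX. LBD16 was lower in DEX by 1.38 ± 0.13 at 4 h and 2.04 ± 0.13 at 6 h and EXPA1 by 1.58 ± 0.27 and 1.98 ± 0.27. LBD29 did not pass (-0.76 and -0.67). GH3.3 fell at 6 h by 0.56 ± 0.18, lost when only the compared groups were fitted and without DEX 6 h replicate 1, 2 or 3 or DMSO 6 h replicate 1 or 3. IAA19 fell by 1.22 ± 0.34, a call lost without DEX 6 h replicate 1 or 3. IAA5 fell at 4 h by 1.47 ± 0.37, lost when only the compared groups were fitted and without DEX 4 h replicate 3 or DMSO 4 h replicate 2, and did not pass at 6 h (-0.86). The DEX and DMSO groups came from separate runs; in the difference to 0 h, in which the runs cancel, 782 genes passed at 4 h and 2338 at 6 h. The 782 were 371, 338 and 1334 without DEX 0 h replicates 1, 2 and 3, 447 without DEX 4 h replicate 1, 323 without DMSO 0 h replicate 3, 357 and 392 without DMSO 4 h replicates 1 and 2 and 166 without the 7 libraries high in photosynthetic RNA. The 2338 were 1507, 1224 and 3530 without DEX 0 h replicates 1, 2 and 3, 1514 and 1452 without DEX 6 h replicates 1 and 3, 1255 without DMSO 0 h replicate 3 and 1151 without the 7 libraries.

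Genes of lateral root initiation were lower in 13 of 25 at 4 h (median -0.76; camera adjusted p = 1e-10, adjusted p = 0.0025 with an estimated correlation) and in 16 of 25 at 6 h in shy2-2 (median -1.09; 5.3e-10, 0.0073 with an estimated correlation), among them PLT7 (AT5G65510), a PLETHORA factor gene, at -4.32 ± 0.34 and LBD17 at -2.13 ± 0.22. When adjusted over the list alone 14 fell at 4 h, and 17 fell and 1 rose at 6 h. DNA replication genes were lower in 10 of 17 at 4 h (11 adjusted over the list alone; median -0.66; 3.7e-07, 0.34 with an estimated correlation). At 6 h 12 of them were lower and 1 higher, such as RNR1 by 1.52 ± 0.20 and PCNA1 (AT1G07370), the sliding clamp gene, by 2.00 ± 0.28 (median -1.11; 3.1e-07, 0.35 with an estimated correlation). Mitosis genes passed in 0 of 18 at 4 h (median -0.24; 0.12) and were lower in 17 of 18 at 6 h, such as CDKB2;1 by 1.94 ± 0.20 and the cyclin gene CYCA2;2 (AT5G11300) by 2.01 ± 0.25 (median -1.25; 8.4e-11, 0.35 with an estimated correlation). Aux/IAA genes rose in 1 and fell in 3 of 28 at 6 h (1 and 2 adjusted over the list alone; 0.61), and auxin transport genes fell in 7 of 16 (0.15). Auxin metabolism genes rose in 3 and fell in 6 of 17 (0.77), with the auxin synthesis gene YUC2 (AT4G13260) at 2.07 ± 0.41 and GH3.1 (AT2G14960) at -1.73 ± 0.35. Cytokinin genes rose in 3 and fell in 3 of 20, heat shock genes fell in 2 of 9 (5 adjusted over the list alone), separation genes in 2 of 6, and root cap genes in 1 of 3. The clock genes rose in 2 of 17, phloem and detoxification genes in 1, endodermis and ethylene genes in 1 (0 adjusted over the list alone), and suberin, root hair, xylem, photosynthesis, and touch, wounding and jasmonate genes in 0. The 2375 genes at 4 h were 1580 without DEX 4 h replicate 3 and 1224 and 1437 without DMSO 4 h replicates 1 and 2. The 4919 at 6 h were 3225 without DEX 6 h replicate 1. When only the compared groups were fitted the counts were 1551 at 4 h and 2101 at 6 h, and without the 7 libraries high in photosynthetic RNA 1396 at 4 h.

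What did DEX change at 4 and 6 h in slr-1? At 4 h 1274 genes were higher and 2622 lower, and at 6 h 2699 higher and 3698 lower in edgeR's quasi-likelihood test. At 6 h AT4G30460 was higher by a log2 fold of 6.76 ± 0.25, MAM1 (AT5G23010), a gene of glucosinolate chain elongation, by 6.19 ± 1.03, AT4G30450 by 5.90 ± 0.24 and NRT1.5 by 5.71 ± 0.29, with SKOR eighth at 5.24 ± 0.25 (n = 3 libraries per group). UMAMIT15 was lower at -7.97 ± 0.43, AT2G15590 at -7.48 ± 0.28, PLT7 at -6.42 ± 0.31 and GATA23 at -5.67 ± 0.24. LBD16 was lower in DEX by 2.25 ± 0.12 at 4 h and 2.06 ± 0.12 at 6 h and EXPA1 by 1.65 ± 0.27 and 1.72 ± 0.27. LBD29 was lower by 1.01 ± 0.16 and 0.74 ± 0.16, and IAA19 by 1.17 ± 0.14 and 1.27 ± 0.14. At 6 h IAA5 fell by 0.96 ± 0.26 and IAA14, fusion reads included, by 0.55 ± 0.09, while GH3.3 did not pass (-0.35).

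In lateral root initiation 18 of 25 genes were lower at both 4 h (median -0.92; camera adjusted p = 6e-13, adjusted p = 0.0082 with an estimated correlation) and 6 h in slr-1 (median -1.09; 8.4e-11, 0.021 with an estimated correlation), with PUCHI at -3.21 ± 0.17 at 6 h. DNA replication genes were lower in 14 of 17 at 4 h (15 adjusted over the list alone; median -0.88; 7.9e-11, 0.21 with an estimated correlation). At 6 h 15 of 17 were lower (16 adjusted over the list alone), among them the licensing helicase gene MCM7 (AT4G02060) at -1.37 ± 0.12 and E2FA (AT2G36010), an S-phase factor gene, at -1.58 ± 0.15 (median -1.2; 1.7e-12, 0.11 with an estimated correlation). Mitosis genes were lower in 4 of 18 at 4 h (0.022, 0.8 with an estimated correlation) and in 18 of 18 at 6 h, such as CYCA2;4 (AT1G80370) by 1.52 ± 0.10 and CDKB2;1 by 2.37 ± 0.17 (median -1.91; 4.3e-16, 0.11 with an estimated correlation). Aux/IAA genes rose in 2 and fell in 8 of 28 at 6 h (3 and 9 adjusted over the list alone; 0.24), and auxin metabolism genes rose in 4 and fell in 4 of 17 (0.85). Auxin transport genes rose in 1 and fell in 5 of 16 (1 and 6 adjusted over the list alone; 0.2). Clock genes rose in 7 of 17 (0.0079, 0.56 with an estimated correlation), cytokinin genes rose in 4 and fell in 3 of 20, endodermis genes rose in 2 of 9 (0 adjusted over the list alone) and phloem genes in 2 of 3 (3 adjusted over the list alone), and xylem, root hair and photosynthesis genes passed in 0. Each DEX group of slr-1 came from another run than its DMSO group.

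**Figure D3:**
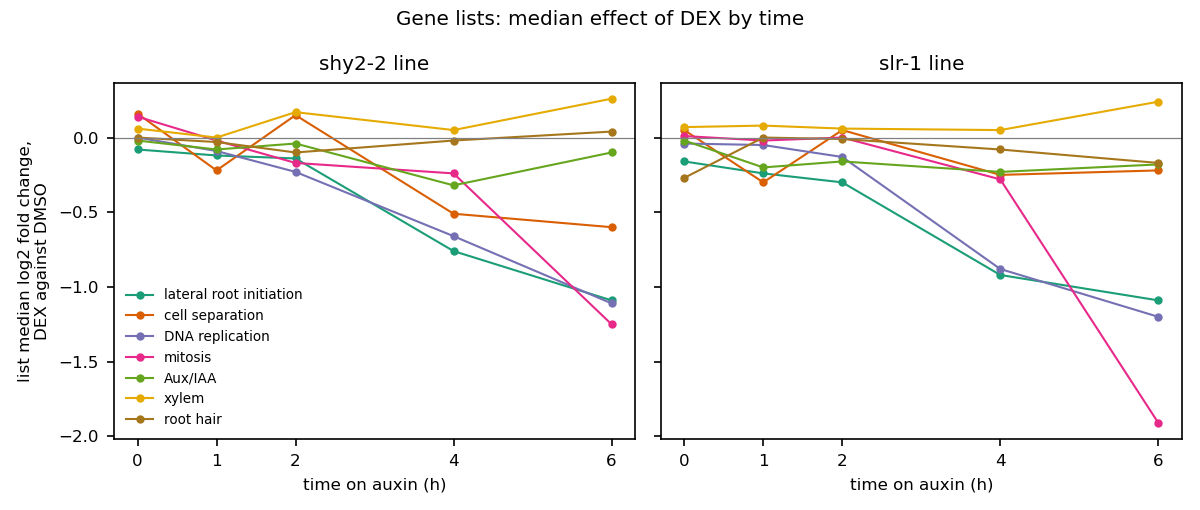
Median log2 fold change of DEX against DMSO (y axis) of 7 gene lists by hours of IAA (x axis) in both lines. Genes of lateral root initiation were at a median of -1.09 at 6 h in both lines, and mitosis genes at -1.25 in shy2-2 and -1.91 in slr-1.

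**Figure D4:**
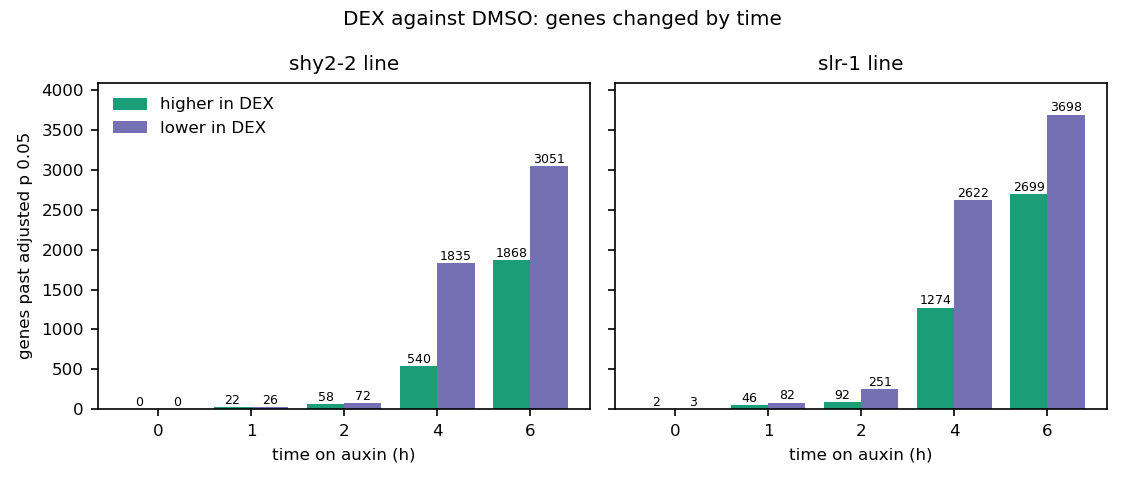
Number of genes higher or lower in DEX than in DMSO (y axis, adjusted p under 0.05) by hours of IAA (x axis) in both lines. In shy2-2 0 genes passed at 0 h and 4919 at 6 h, and in slr-1 5 and 6397.

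Was the auxin response itself changed by DEX? In shy2-2, where each arm of the mean of 2, 4 and 6 h minus 0 h lay within a run, the response was more positive under DEX in 205 genes and more negative in 807 in edgeR's quasi-likelihood test. AT4G30460 stood at 3.18 ± 0.30 and SKOR at 3.15 ± 0.23 (n = 3 libraries per group). At the other end AT1G09310 stood at -4.65 ± 1.34, a call lost in 16 of the fits without 1 library (-4.73 to -1.31). These lacked DEX 0 h replicate 2, 2 h replicate 1, 2 or 3, 4 h replicate 1 or 2, 6 h replicate 1 or 3, or DMSO 0 h replicate 2 or 3, 2 h replicate 2, 4 h replicate 1 or 2, 6 h replicate 1, 2 or 3. Next were LBD33 at -3.14 ± 0.64, lost without shy2-2 DEX 0 h replicate 1, and FLP at -2.83 ± 0.15. LBD16 was at -1.07 ± 0.16 and EXPA1 at -1.12 ± 0.31, while GATA23 did not pass (-1.88 ± 1.21). In DEX at 0 h GATA23 held only 2 counts, so its change was poorly measured and an unchanged response is not shown. The call of EXPA1 was lost without the 7 libraries high in photosynthetic RNA, without a filter and in 14 of the fits without 1 library (-1.22 to -0.89). These lacked DEX 0 h replicate 1 or 2, 2 h replicate 1 or 3, 6 h replicate 1 or 3, or DMSO 0 h replicate 1, 2 or 3, 2 h replicate 3, 4 h replicate 1 or 2, 6 h replicate 2 or 3. More negative were 6 of 25 genes of lateral root initiation (8 adjusted over the list alone; camera adjusted p = 3.6e-07, adjusted p = 0.031 with an estimated correlation), 5 of 17 of DNA replication (12 adjusted over the list alone; 1.2e-06, 0.51 with an estimated correlation) and 2 of 18 of mitosis (9 adjusted over the list alone; 6.5e-07, 0.56 with an estimated correlation). The 1944 genes that rose with auxin in slr-1 had a median log2 fold of 1.61 in DMSO and 1.26 in DEX of shy2-2. Of these genes 283 passed, 275 of them with a weaker response. The count of 1012 was 479, 327 and 1980 without shy2-2 DEX 0 h replicates 1, 2 and 3, 348 without DMSO 0 h replicate 3 and 313 without the 7 libraries.

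In slr-1 the response was more positive under DEX in 719 genes and more negative in 1736. Here each arm spanned 2 runs, so this contrast is confounded with run. AT4G30460 stood at 4.64 ± 0.23 and SKOR at 4.59 ± 0.25. The largest falls at 5 CPM or more were the photosynthesis genes CA1 (AT3G01500) at -8.98 ± 2.39 and FBA1 (AT2G21330) at -7.73 ± 1.88. Both calls were lost without the 7 libraries high in photosynthetic RNA, a fit that leaves slr-1 DEX 0 h and DMSO 2 h with 1 library each. The call of CA1 was also lost without slr-1 DMSO 0 h replicate 2 or 3. LBD16 was at -1.31 ± 0.15 and IAA19 at -1.10 ± 0.17, while the calls of EXPA1 at -1.45 ± 0.32 and LBD29 at -1.07 ± 0.27 were lost without the 7 libraries, and that of LBD29 also without slr-1 DMSO 0 h replicate 2. Genes of lateral root initiation rose in 1 and fell in 9 of 25 (1 and 11 adjusted over the list alone; camera adjusted p = 4.4e-07, adjusted p = 0.11 with an estimated correlation). DNA replication genes fell in 10 of 17 (13 adjusted over the list alone; 6.3e-08, 0.33 with an estimated correlation) and mitosis genes in 8 of 18 (12 adjusted over the list alone; 1.4e-06, 0.62 with an estimated correlation). The 1716 genes that rose with auxin in shy2-2 had a median log2 fold of 1.83 in DMSO and 1.4 in DEX of slr-1, and 272 of the 280 that passed had a weaker response.

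Did the lines differ? Of 21588 genes tested in both, 1046 were higher in DEX at 6 h in both lines, with 233 expected by chance. Lower in both were 2447, with 512 expected, and 6 went opposite ways. The differences between the lines given next are confounded with run at every time, since no DEX group of slr-1 shared a run with its DMSO group. In a direct test of the difference, LBD16 was less lowered by DEX in shy2-2 than in slr-1 at 4 h, by a log2 fold of 0.91 ± 0.17 (95% interval 0.56 to 1.26, n = 3 libraries per group, adjusted p = 0.005 in edgeR's quasi-likelihood test), and did not differ at 6 h (0.06, -0.29 to 0.41). At 4 h 7 genes stood higher and 25 lower in shy2-2 less slr-1. Among those with a mean of at least 5 CPM the extremes were AT2G42150 at 2.98 ± 0.42 and SKOR at -3.16 ± 0.33. At 6 h 8 stood higher and 33 lower, and AT2G07875 was the lowest with a mean of at least 5 CPM, at -2.96 ± 0.57. Its sign did not hold with counts of both strands (0.1), and its call was lost without shy2-2 DMSO 6 h replicate 1. The call of LBD16 at 4 h was lost without shy2-2 DEX 4 h replicate 2 (0.78). Some genes passed at both 4 and 6 h, each with the same sign at both times. Among them, chosen after their values were seen, were AT1G31050 at -1.24 ± 0.17 and -1.22 ± 0.17 and PLT7 at 2.76 ± 0.43 and 2.14 ± 0.45. Each group of 4 h shared its run with the same group of 6 h, so a difference between runs could also repeat. The 41 genes at 6 h were 21 without shy2-2 DEX 6 h replicate 1, 15 and 122 without shy2-2 DMSO 6 h replicates 1 and 2, 18 without slr-1 DEX 6 h replicate 2 and 27 without slr-1 DMSO 6 h replicate 2.

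In the change of the auxin response by DEX 2 genes differed between the lines: ATSBT5.2 (AT1G20160), a subtilase gene, at -1.53 ± 0.26 and AT1G31050 at -1.05 ± 0.19. Both calls were lost without the 7 libraries high in photosynthetic RNA. The count was 0 without shy2-2 DEX 0 h replicate 1 or 2, shy2-2 DMSO 0 h replicate 2, slr-1 DEX 0 h replicate 1 or slr-1 DMSO 0 h replicate 1, and 1 without shy2-2 DMSO 0 h replicate 1 or slr-1 DMSO 0 h replicate 3. At 0 and 1 h edgeR's quasi-likelihood test called 0 genes for the difference between the lines in DEX against DMSO. At unadjusted p under 0.05 were 292 and 162 of 22268 genes, fewer than chance alone would give. The test may thus be too strict here, and its 0 calls do not show that the lines were alike. At 2 h edgeR's test called 1 gene, AT2G42150 at 2.79 ± 0.43.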

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

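Chosen only after the results were seen were the run-free count at 6 h and its repeats without libraries, the signs of the calls against the auxin response of the other line, the medians of genes raised or lowered by auxin there, the search for groups with all libraries above the mark, the look at the glucosinolate list in the change of the auxin response (over 2, 4 and 6 h and at 6 h alone) and without single libraries, and the differences between the lines at 4 and 6 h.

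LBD16 was less lowered by DEX in shy2-2 than in slr-1 at 4 h, by a log2 fold of 0.91, and at 6 h the lines did not differ (0.06). In the change of the auxin response by DEX, ATSBT5.2 differed between the lines at -1.53 and AT1G31050 at -1.05. These 3 differences came from a direct test between the lines, but no DEX group of slr-1 shared a run with its DMSO group. Those of ATSBT5.2 and AT1G31050 cannot be told apart from a difference between runs. For LBD16 each group of 4 h shared its run with the same group of 6 h. A constant run difference would be equal at both times. The 95% intervals, 0.56 to 1.26 and -0.29 to 0.41, do not overlap, which argues against it as the only source of the value at 4 h. The difference between the times was not itself tested. At 2 h, on the same runs, the value was 0.53 (0.18 to 0.88) and did not pass. The value at 4 h, a call lost without shy2-2 DEX 4 h replicate 2, may still contain a run difference. When the line labels were shuffled at random within each treatment and time, 7 of 60 splits called at least the real 32 genes at 4 h (highest other 380), 11 of 60 the real 41 at 6 h (highest other 552) and 7 of 60 the real 2 for the change of the auxin response (highest other 371). Lines were shuffled in each treatment and time separately. A difference between lines common to DEX and DMSO therefore cancels in the real contrast but not in a shuffled split. For this reason the shuffle cannot decide the question, and chance assignment of the samples to lines is neither supported nor excluded by it.

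DEX changed more genes the longer auxin had been present. A difference between sequencing runs is one candidate explanation. In shy2-2 a run difference that is the same at 0 and 6 h cancels in the DEX effect at 6 h minus that at 0 h. This contrast called 2338 genes, so such a run difference alone does not account for the 4919 called at 6 h. That count was 1507, 1224 and 3530 without DEX 0 h replicates 1, 2 and 3, 1514 and 1452 without DEX 6 h replicates 1 and 3, 1255 without DMSO 0 h replicate 3 and 1151 without the 7 libraries high in photosynthetic RNA. For slr-1, 95.4% of the genes called at 6 h had the same sign in the run-free contrast of shy2-2, so a difference between runs that is the same at all times does not account for most of the signs. A run difference that varies between times was not tested. A weaker auxin response under DEX could account for part of the growth. Of the calls at 6 h, 86.3% in shy2-2 and 85.4% in slr-1 had the sign opposite to the auxin response at 6 h in DMSO of the other line, against 60.4 and 61.9% of the genes not called. The genes that rose with auxin in the other line had a median log2 fold of DEX against DMSO of -0.59 in shy2-2 and -0.38 in slr-1 at 6 h, and those that fell 0.2 and 0.44. The calls with the same sign as the auxin response are not explained by it. An effect of DEX itself that grows with time stays open, as no plants without the fusion gene were treated.

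Photosynthetic RNA was high in 7 libraries. RNA from shoot tissue is a likely explanation, since 6 of the 7 libraries highest in shoot identity genes were among them. Treatment or time alone does not account for it, since libraries of the same group lay far apart: 8.15, 4.54 and 5.4 in shy2-2 DEX 0 h, 8.1, 4.36 and 3.73 in shy2-2 DMSO 2 h, and 8.01, 7.43 and 4.81 in slr-1 DEX 0 h. The number of groups with all 3 libraries above the mark was 0.

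Aliphatic glucosinolate genes were higher under DEX at 6 h in slr-1. Whether the change is found only in the line where it was noticed stays open. The median of the list was 1.87 in shy2-2 at 6 h, but only 5 of 19 genes rose and camera's adjusted p was 0.00042 with the preset and 0.37 with an estimated correlation. Camera's p-values of this list were adjusted over the 2 lists added later, not over those of the other tests. The bound set before the test, a median above 0.2 with camera's preset p under 0.05, was met, but it left out that the DEX and DMSO libraries came from separate runs. In the change of the auxin response of shy2-2 at 6 h, in which the runs cancel, the median was 0.77 and 1 of 19 genes passed, MYB28 at 1.68 ± 0.50 (camera adjusted p = 0.14, adjusted p = 0.71 with an estimated correlation). Over the mean of 2, 4 and 6 h it was 0.18 with 0 genes (0.56). The medians also hung on single libraries: that of DEX against DMSO at 6 h was 0.8 without DEX 6 h replicate 2. The median at 0 h was 0.93 with all libraries and 0.01 without DEX 0 h replicate 1. Without DMSO 0 h replicates 1 and 2 in turn it was 0.51 and 1.91, and without the 7 libraries high in photosynthetic RNA 1.06. The source of the value at 0 h was not found.

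For every DEX against DMSO and every auxin comparison of 3 against 3 libraries only 10 splits exist, so the share of splits with a count as large can never be under 0.1. In all of them except DEX at 0 h in shy2-2 only the real split, 1 of 10, reached its count; the highest other count was 5 for auxin at 6 h in shy2-2, 3 for DEX at 0 h in slr-1, 1 for DEX at 2 h in slr-1 and 0 in the rest. For DEX at 0 h in shy2-2 the real count was 0 and another split called 1029, which points to a structure of the samples; its source was not tested. For the change of the auxin response by DEX 1 of 100 splits reached the real count in each line, with a highest other of 78 in shy2-2 and 1794 in slr-1. Here DEX and DMSO were shuffled at each time separately. A difference between them common to all times therefore cancels in the real contrast but not in a shuffled split. For this reason the shuffle cannot decide if these counts arose by chance.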

How the results depend on the processing

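The alternatives marked as added after were chosen once the data had been seen. RLE factors, no filter, the replicate block and counts of both strands (added after) kept every count of changed genes within 1.5-fold. With the replicate block DEX in shy2-2 gave 55 genes at 1 h (48 before) and 2537 at 4 h (2375 before). In slr-1 it gave 415 at 2 h (343 before), 4313 at 4 h (3896 before) and 7040 at 6 h (6397 before). The mean correlation between libraries of the same replicate number was 0.027 in shy2-2 and 0.01 in slr-1. Between other numbers it was -0.013 and -0.004. Yet 16 and 14 of 30 libraries fitted best with their own number, more than random numbering would give. A partial pairing by number therefore stays open. DESeq2 called more for DEX against DMSO: 6, 118 and 260 at 0, 1 and 2 h in shy2-2, and 90, 212 and 516 in slr-1. For the line difference at 4 and 6 h it called 51 and 86; the cause was not tested. A fit of only the compared groups, which has fewer residual degrees of freedom, gave 7, 21, 1551 and 2101 genes at 1, 2, 4 and 6 h in shy2-2. In slr-1 it gave 0 (651 at unadjusted p under 0.05), 28 and 100 at 0, 1 and 2 h. At 0 h in shy2-2 edgeR's quasi-likelihood test called 0 genes in all of these, with 903 at unadjusted p under 0.05 without a filter, 730 with RLE, 670 with the block, 694 with both strands, 328 with only the compared groups and 320 without the 7 libraries. The fit without the 7 libraries high in photosynthetic RNA (added after) leaves slr-1 DEX 0 h and DMSO 2 h with 1 library, assumed to vary like the other groups. There counts were 4412 for auxin at 2 h in slr-1, 2 and 151 for DEX at 0 and 2 h in slr-1, 846 for the change of the auxin response in slr-1 and 313 in shy2-2, 1396 for DEX at 4 h in shy2-2 and 0 for the line difference (391 at unadjusted p under 0.05). Also there RBCS2B (AT5G38420) went to -1.21 in the auxin response of slr-1 at 2 h, and CAB3 to 0.06 and FBA2 (AT4G38970) to 0 in the change of that response. With counts of both strands AT2G07875 was at 0.1 in the line difference at 6 h. With an estimated correlation between genes 32 of 420 list tests passed, against 116. When 1 library was left out, DEX in shy2-2 gave 0 to 2 genes at 0 h, 52 to 100 at 2 h, 1224 to 2189 at 4 h and 3225 to 5187 at 6 h. DEX in slr-1 gave 2 to 160, 71 to 152 and 166 to 356 at 0, 1 and 2 h. The change of the auxin response in shy2-2 gave 327 to 1980, and the line difference 0 to 3 in that change and 15 to 122 at 6 h. Of 1221 values of named genes, DESeq2 kept 1213, RLE 1211, the block 1212, no filter 1191 and the fit without the 7 libraries 1122. The fit of only the compared groups kept 1035 of 1159 and lost 121 calls, and the fits without 1 library lost 695 of 9768.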

Other observations

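The 2 lists in this part were chosen only after the results were seen, because some of their members ranked among the genes highest in DEX. No test of a list as a whole is therefore given for the libraries in which it was noticed. Values and counts of members from those libraries are a description and not evidence for the list. Transporter genes of the stele were collected around SKOR, NRT1.5 and HMA2. Of the 4 added to them, PHO1 (AT3G23430), a gene of phosphate export to the xylem, was higher in DEX at 6 h by a log2 fold of 2.26 ± 0.17 in shy2-2 and 3.55 ± 0.15 in slr-1, and the zinc exporter gene HMA4 (AT2G19110) by 1.04 ± 0.14 and 1.60 ± 0.19. The sodium transporter gene HKT1 (AT4G10310) passed in slr-1 (3.03 ± 0.45) and not in shy2-2 (1.58 ± 0.63), and BOR1 (AT2G47160), a boron exporter gene, passed in neither (0.28 and 0.30). With auxin in DMSO 6 of the 7 genes fell at 6 h in both lines. That contrast shares its DMSO 6 h libraries with DEX against DMSO, so the fall is not separate evidence.

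Genes of aliphatic glucosinolate synthesis rose under DEX in 17 of 19 at 6 h in slr-1 and fell in 1 (median 4.14), among them the regulator gene MYB28 (AT5G61420) at 4.14 ± 0.47 and MAM1 at 6.19 ± 1.03. In shy2-2 they rose in 5 of 19 and fell in 1 (median 1.87; camera adjusted p = 0.00042, adjusted p = 0.37 with an estimated correlation). These 6 calls were 2 without DEX 6 h replicate 2, 3 without DMSO 6 h replicate 1 and 2 without DMSO 6 h replicate 3. With auxin in DMSO at 6 h 16 of 19 fell in slr-1 (median -2.96) and 1 of 19 in shy2-2 (median -0.3, camera adjusted p = 0.5). In slr-1 the same DMSO 6 h libraries enter the rise under DEX and this fall, so the fall is not separate evidence.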
